A study of Mus musculus with 12 samples.

How the data were processed

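RNA was profiled by 3′-end RNA sequencing in 12 mouse libraries, 2 in each of 6 groups. Total RNA was extracted with a column kit and its cDNA was amplified before libraries were made for a SOLiD instrument. The labels give 10 ng of RNA for each library of primordial germ cell-like cells (PGCLCs) and 1 ng for each embryonic library. They also give different strains, reporters and sorts: PGCLCs were C57BL/6 cells sorted by Blimp1-mVenus fluorescence, and embryonic cells came from a mix of ICR and C57BL/6 and were sorted by Stella-EGFP fluorescence. The comparison of culture with embryo is therefore confounded with strain, reporter, sort and RNA input. Replicate numbers name no shared day, batch or animal, so they were not used as a pairing.

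The deposited table holds RPM, read numbers that the authors scaled to the sum of reads assigned to genes. The submitters' notes name cutadapt 1.3, TopHat 1.4.1, Cufflinks 2.2.0 and the genome build mm10, without saying which step each served. The table has 26218 gene rows and 92 rows for ERCC spike-in RNAs, of which 24 are empty in every library. It has no row on chromosome Y and no mitochondrial gene. Within each library most low values are multiples of a smallest step, which was taken as the RPM of 1 read. Between 85.0% and 91.2% of the values up to 20 reads were whole multiples within 0.1 read. Whole reads were therefore not recovered, and tests on counts were not used here. From the steps, reads in genes were estimated at 2219175 to 5817990 per library. A value of 0 allows up to 3 reads, which is 0.517 RPM in the deepest library and 1.36 RPM in the shallowest. These floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

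Gene positions and NCBI gene identifiers were taken from the RefSeq annotation of GRCm38.p6, the same build as mm10. Of the 26218 gene rows, 24619 were matched by identifier, and of the tested genes 10497 were matched.

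Values were analysed as log2(RPM + 1). Genes were tested where RPM was at least 5 in at least 2 of the 12 libraries, which kept 10856 genes and left out 15362. All 12 libraries entered a single limma 3.58.1 model in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) with a mean per group. The model had 6 residual degrees of freedom and 8.02 prior degrees of freedom. Each contrast was adjusted by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Group values are means ± SD of 2 libraries. The error of a log2 change is its standard error (SE) from the model. Tested on simulated data built from these groups, the model recovered 48% to 63% of genes changed by 1 on the log2 scale. It recovered 89% to 99% of genes changed by 2, with 5 to 15 false calls per contrast. The simulated noise was normal, independent and of equal spread in all groups. In the data, replicates differed by a root mean square of 0.33 (E9.5) to 0.56 (d4c7) on the log2 scale. These rates may therefore not hold for the culture contrasts.

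The samples compared, the lists of genes, the rule for naming genes and the alternatives were fixed before the data were examined, except where an addition is stated. The 24 fixed lists held 394 entries, of which 386 had a row and 306 were tested. They covered primordial germ cell (PGC) specification, pluripotency, late germ cells, meiosis, male germ cell fate, the piRNA pathway, DNA methylation, DNA demethylation and base excision repair, histone H3K9 methylation, Polycomb, imprinted genes, cell cycle, cAMP response, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid and unfolded protein stress, and p53 targets. Further lists stood for other cells that a sort could hold: gastrulation and somatic mesoderm, gonadal somatic cells, hindgut and endoderm, blood and endothelium, and fibroblast and stromal feeder. None of the 8 Y-linked genes of the last list had a row. X-linked genes, 409 of them tested, were compared between the sexes.

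Each list with at least 4 tested genes was tested per contrast with camera of limma, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of the contrast. Late germ cell and piRNA lists share 6 tested genes, and the male germ cell fate list shares 1 with each of the DNA methylation and piRNA lists. The X-linked genes share 1 with each of 9 other lists. Counts of called list members were made over all genes tested and adjusted over the list alone. Genes named per contrast were up to 4 called members of each described list with the largest change, the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap and whose higher mean was at least 50 RPM, and 9 germ cell genes always reported. Of these 9, Nanos2 and Xist did not pass the filter and were not tested. Predicted genes were left out of the naming. Some genes that the rule names are not described here.

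Alternatives were other pseudocounts, filters, scalings and variance models, a fit over the 4 libraries compared, replicate number as a block, a fold threshold, an estimated correlation, and leaving out each library in turn. In the last, the lone library of a group was assumed to vary like the other groups. A block within culture libraries only and a fit without chromosomes 3 and 16 were added after the data were seen. Later tests used added marker lists, 10000 random lists matched on expression or on expression and GC content of the last 500 bases of each transcript, and medians over chromosomes and over 4 equal parts of each, taken over genes with a mean of at least 20 RPM. These tests and the figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.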

Results

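The data are 12 libraries of 3′-end RNA sequencing from mouse germ cells, 2 per group. PGCLCs are made from embryonic stem cells through an epiblast-like state. They were sorted at day 4 of induction and expanded on a layer of m220 stromal feeder cells, and were sorted again at culture day 3, 5 or 7, as the group names d4c3, d4c5 and d4c7 say. The embryonic groups are PGCs of embryonic day (E) 9.5, a stage of migration, and male and female germ cells of E12.5, when they have reached the gonad. Depth, estimated from the steps of the deposited values, ranged from 2219175 reads in genes in d4c5 replicate 2 to 5817990 in d4c7 replicate 2. Between 9324 and 9694 genes per library had at least 5 RPM. Labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples. The model pools that spread over all 6 groups. Replicates differed by a root mean square of 0.42 to 0.56 on the log2 scale in culture and of 0.33 to 0.40 in the embryo. The SE and p-values of culture contrasts may therefore be too small.

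The reporter genes used for sorting were expressed in all groups. Prdm1, which encodes the transcription factor Blimp1, was at 110 ± 4.59 RPM in d4c3, 104 ± 22.5 RPM in d4c7 and 66.8 ± 2.48 RPM at E9.5 (SD, n = 2 for every group value). Dppa3, which encodes Stella, was at 1321 ± 15.4 RPM in d4c3, 1500.2 ± 260.5 RPM in d4c7, 2051 ± 53.8 RPM at E9.5, 4808 ± 53.6 RPM in males and 2916 ± 72.5 RPM in females. Across genes, libraries of the same group correlated at Pearson r from 0.965 (d4c7) to 0.986 (E9.5), and genes are not independent replicates. In principal components, the first (40.4% of variance) separated the 6 PGCLC libraries from the 6 embryonic libraries and the second (28.2%) set E9.5 apart from the other groups.

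**Figure D1:**
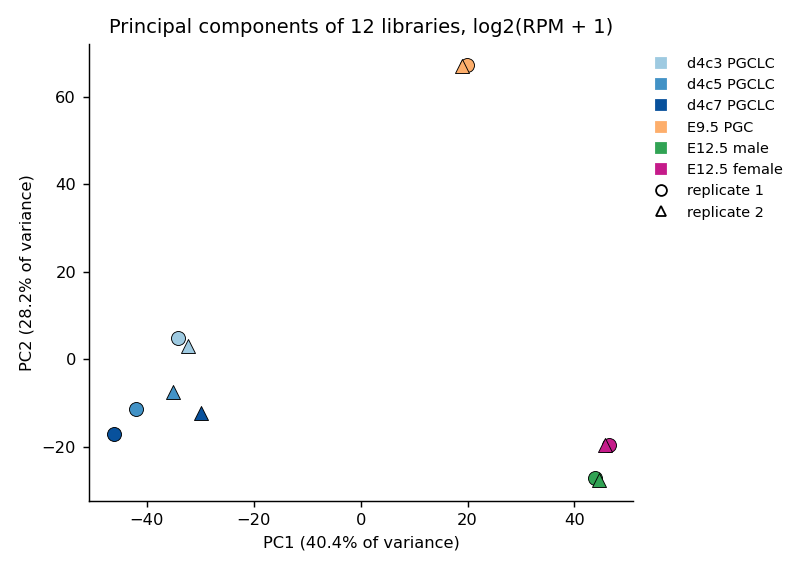
Scores of the 12 libraries on the first and second principal components of log2(RPM + 1), coloured by group and shaped by replicate number. PGCLC libraries have negative scores on the first component (40.4% of variance), and the E9.5 libraries have the highest scores on the second (28.2%).

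The first comparison asked what changes in PGCLCs over expansion culture, from d4c3 to d4c7. Dazl, which encodes an RNA-binding protein needed for germ cell development, rose from 31.8 ± 1.00 RPM to 400.3 ± 147 RPM, a log2 change of 3.56 ± 0.29 (SE). Hormad1, a component of the meiotic chromosome axis, rose from 8.76 ± 0.779 RPM to 58.6 ± 14.9 RPM. Stra8, a retinoic acid-induced gene of meiotic entry, rose from 0.222 ± 0.314 RPM to 9.89 ± 1.56 RPM, and the meiotic cohesin gene Smc1b rose from 13.1 ± 0.873 RPM to 41.9 ± 0.215 RPM. Dnmt3l, the cofactor of de novo DNA methyltransferases, rose from 8.08 ± 8.65 RPM to 110 ± 97.0 RPM, with 178 RPM in d4c7 replicate 1 and 41.0 RPM in replicate 2.

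Other genes fell over the same span. Phlda2, an imprinted growth restrictor, fell from 191 ± 24.9 RPM to 26.7 ± 3.26 RPM (log2 change -2.79 ± 0.14), with 60.2 ± 5.25 RPM at d4c5 between them. Igf2, an imprinted growth factor gene, fell from 13.5 ± 0.861 RPM to 2.31 ± 1.60 RPM. Dnd1, which encodes an RNA-binding protein needed for PGC survival, fell from 139 ± 15.9 RPM to 56.0 ± 9.78 RPM. Hmgn5, which encodes a nucleosome-binding protein, fell from 262 ± 12.6 RPM to 78.8 ± 0.931 RPM.

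In all, 298 of 10856 genes were called between d4c7 and d4c3, 181 higher and 117 lower, and 199 of them changed at least 2-fold. Among late germ cell genes 6 of 17 rose (camera, adjusted p = 1.15e-10, and adjusted p = 0.140 with an estimated correlation). Adjusted over the list alone, 12 rose. Of 12 piRNA pathway genes, which include 6 of the late germ cell genes, 2 rose (adjusted p = 0.000183, and adjusted p = 0.171 with an estimated correlation; 5 adjusted over the list alone). They were Ddx4, the germ cell helicase, from 46.6 ± 5.51 RPM to 98.5 ± 27.8 RPM, and Piwil2, a Piwi protein gene, from 48.8 ± 5.66 RPM to 94.2 ± 19.4 RPM. Of 16 meiosis genes 3 rose, namely Stra8, Smc1b and the cohesin gene Stag3, and Syce2 of the synaptonemal complex fell from 404 ± 23.8 RPM to 293 ± 16.4 RPM (adjusted p = 0.00216, and adjusted p = 0.101 with an estimated correlation). Adjusted over the list alone, 5 were higher and 1 lower.

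All 12 targets of the tumour suppressor p53 had higher means at d4c7 than at d4c3, and 5 of them were called (adjusted p = 5.30e-09, and adjusted p = 0.101 with an estimated correlation; 9 adjusted over the list alone). Trp53inp1, a stress-induced p53 target, rose from 137 ± 4.84 RPM to 237 ± 0.125 RPM. Pmaip1, the pro-apoptotic gene known as Noxa, rose from 8.69 ± 4.54 RPM to 29.9 ± 7.44 RPM, and Phlda3, an inhibitor of Akt signalling, from 22.3 ± 4.92 RPM to 48.6 ± 1.23 RPM. Male germ cell fate genes were shifted upward (3 of 7 called, the same 3 adjusted over the list alone; adjusted p = 0.0489, and adjusted p = 0.297 with an estimated correlation). The 3 were Dnmt3l and the Nodal antagonist genes Lefty1, from 27.2 ± 0.228 RPM to 62.4 ± 6.45 RPM, and Lefty2. The list did not pass without d4c3 replicate 2 (adjusted p = 0.0658) or d4c7 replicate 1 (adjusted p = 0.264). Imprinted genes were shifted downward with 2 of 22 called, Phlda2 and Igf2 (adjusted p = 0.0393, and adjusted p = 0.159 with an estimated correlation; 6 adjusted over the list alone), and did not pass without d4c3 replicate 1 (adjusted p = 0.120) or d4c7 replicate 2 (adjusted p = 0.235). Of 18 pluripotency genes Fgf4, which encodes a growth factor of the epiblast, was called, from 0.613 ± 0.240 RPM to 9.30 ± 4.62 RPM.

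The number of genes called rested on single libraries: 31 without d4c3 replicate 1, 140 without d4c3 replicate 2, and 786 without d4c7 replicate 2, where 329 were higher and 457 lower. A limma fit over the 4 libraries compared called 0 genes (1084 at an unadjusted p under 0.05), and a fit of the culture libraries with replicate as a block called 32. Of 40 named genes called, 12 kept the call with every library left out in turn, among them Dazl, Hormad1, Stra8, Smc1b, Phlda2, Dnd1, Hmgn5 and Fgf4. The other 28 lost it without at least 1 library. Without d4c3 replicate 1 the adjusted p was 0.0561 for Trp53inp1, 0.250 for Pmaip1, 0.281 for Phlda3, 0.107 for Ddx4 and for Igf2, 0.0553 for Piwil2, 0.150 for Stag3, 0.126 for Syce2, 0.121 for Lefty1, 0.350 for Lefty2 and 0.173 for Dnmt3l.

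Within that span, the change from d4c3 to d4c5 had 9 called genes, 7 higher and 2 lower, with 967 genes at an unadjusted p under 0.05. Dazl rose to 273 ± 145 RPM, Hormad1 to 32.2 ± 11.4 RPM and Fkbp6, which encodes a piRNA pathway co-chaperone, from 21.5 ± 0.0279 RPM to 50.6 ± 13.1 RPM, and Phlda2 fell. Late germ cell genes, p53 targets and piRNA genes were shifted upward in camera, at adjusted p of 3.89e-11, 1.43e-06 and 0.000285, and each had adjusted p = 0.188 with an estimated correlation. Called were 2 of 17 late germ cell genes and 0 of 12 in the other lists, against 6, 4 and 4 adjusted over the list alone. From d4c5 to d4c7 limma called 2 genes, with 610 at an unadjusted p under 0.05: Stra8 rose from 0.421 ± 0.0439 RPM, and Phlda2 fell. The p53 targets were again shifted upward with 0 of 12 called and 0 adjusted over the list alone (adjusted p = 0.00533, and adjusted p = 0.527 with an estimated correlation). Leaving out d4c5 replicate 2 gave 26 calls for the first step, the other libraries 2 or 3, and Hormad1 (adjusted p = 0.277) and Fkbp6 (0.265) lost the call without d4c3 replicate 1. For the second step, leaving out d4c7 replicate 1 gave 30 calls, and limma called 0 without d4c5 replicate 1 or replicate 2 (736 and 519 genes at an unadjusted p under 0.05; adjusted p of Stra8 0.0739 and 0.147, of Phlda2 0.0739 and 0.0594). In the same 2 other fits limma called 0 genes for either step (805 and 262 at an unadjusted p under 0.05 over the 4 libraries, 941 and 535 with the block). The p53 list was not shifted in the second step without d4c5 replicate 2 (adjusted p = 0.155) or d4c7 replicate 1 (adjusted p = 0.685).

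**Figure D2:**
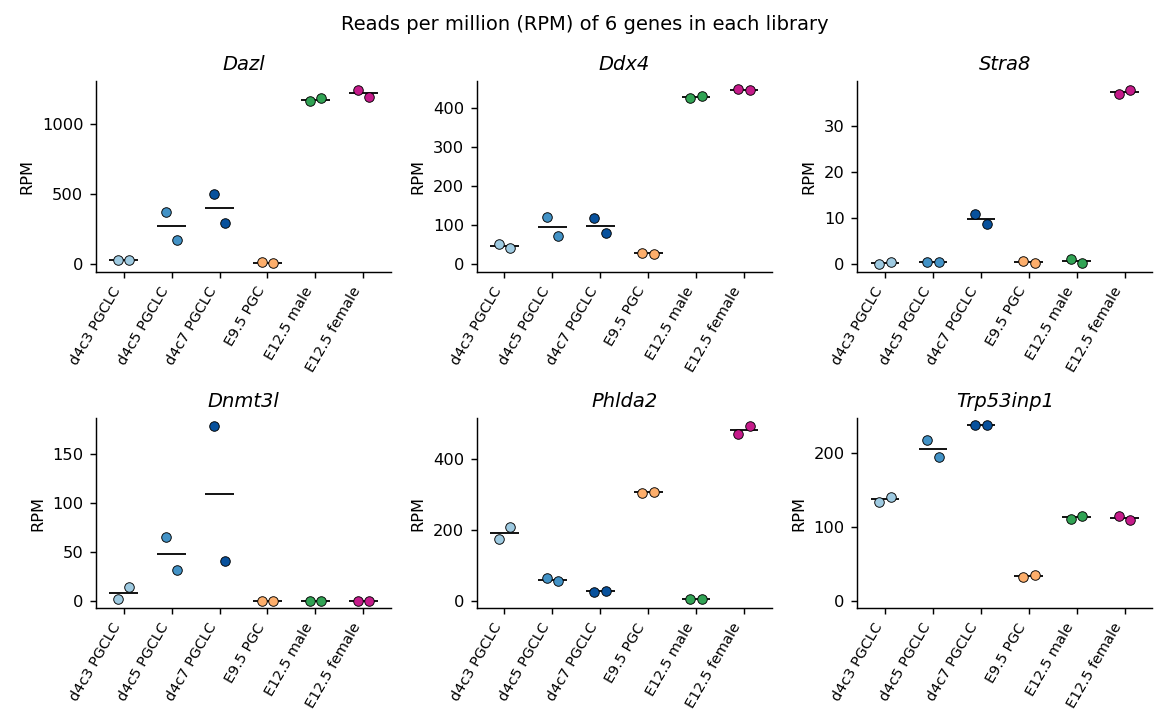
RPM of Dazl, Ddx4, Stra8, Dnmt3l, Phlda2 and Trp53inp1 in each of the 12 libraries, with points for libraries and bars for the means of 2. Dnmt3l is at 0 in all 6 embryonic libraries and at 178 RPM and 41.0 RPM in d4c7, and Phlda2 is at 479 ± 15.5 RPM in E12.5 females and 5.67 ± 0.0661 RPM in males.

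The embryonic comparisons asked how male and female germ cells of E12.5 differ from the PGCs of E9.5. The E9.5 group is not split by sex, and its sex could not be read since no Y-linked gene had a row. The contrasts are therefore not changes within a single sex. Spike-in sums also differed between the stages, as described below, so a difference in library preparation was not separated from stage. Genes of the later germ cell programme rose in both sexes. Dazl (NCBI gene 13164, GRCm38.p6 chromosome 17, 50279393 to 50293620) rose from 11.2 ± 2.43 RPM to 1174 ± 15.4 RPM in males and 1218 ± 38.2 RPM in females, log2 changes of 6.61 and 6.66. Ddx4 (NCBI gene 13206, chromosome 13, 112598333 to 112652633) rose from 28.3 ± 2.32 RPM to 427 ± 2.98 RPM and 446 ± 1.01 RPM. The piRNA pathway gene Mael rose from 4.13 ± 1.16 RPM to 149.5 ± 5.79 RPM and 188 ± 14.9 RPM. In females, Stra8 (NCBI gene 20899, chromosome 6, 34920163 to 34939344) also rose, from 0.486 ± 0.353 RPM to 37.5 ± 0.695 RPM, and it was at 0.776 ± 0.671 RPM in males.

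In males, Lefty1 rose from 7.74 ± 1.27 RPM to 187 ± 11.9 RPM, and Lefty2 (NCBI gene 320202, chromosome 1, 180893108 to 180899107) from 12.7 ± 1.06 RPM to 253 ± 15.9 RPM. In females Lefty1 fell to 3.10 ± 0.952 RPM and Lefty2 to 1.56 ± 0.789 RPM. Phlda2 (NCBI gene 22113, chromosome 7, 143501545 to 143503145) fell from 305 ± 0.913 RPM to 5.67 ± 0.0661 RPM in males. The imprinted growth regulator gene Grb10 fell from 146 ± 0.892 RPM to 3.24 ± 1.60 RPM in males and 6.90 ± 1.62 RPM in females. Ldha, which encodes lactate dehydrogenase (NCBI gene 16828, chromosome 7, 46842274 to 46855627), fell from 630.0 ± 14.2 RPM to 25.0 ± 2.16 RPM and 71.2 ± 6.56 RPM. The interferon-induced PGC marker gene Ifitm3 fell from 1023 ± 41.6 RPM to 215 ± 4.76 RPM and 278 ± 5.84 RPM.

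In males 4089 genes were called (2176 higher, 1913 lower) and in females 4069 (2216 higher, 1853 lower), with 2067 and 1993 of them changed at least 2-fold. Which direction had more genes depended on the settings. With medians of log ratios set to 0 there were 1829 higher and 2211 lower in males and 1949 and 2141 in females, and without a filter 2091 and 2440, and 2075 and 2248. All 17 late germ cell genes rose in males and 16 in females (camera, adjusted p = 7.05e-15 and 9.01e-16), and 11 of 12 piRNA genes rose in each sex (adjusted p = 2.74e-08 and 1.05e-08). Counts were the same adjusted over the list alone. With an estimated correlation both lists had adjusted p = 0.0373 in males and 0.0317 in females. Of 16 meiosis genes 9 rose and 2 fell in males (adjusted p = 0.00166; 10 and 2 adjusted over the list alone). In females 13 rose and 1 fell (adjusted p = 2.08e-07; the same adjusted over the list alone). Both calls held with an estimated correlation (adjusted p = 0.0373 and 0.0240). Male fate genes went opposite ways, with 5 of 7 higher and 1 lower in males and 4 of 7 lower in females, the same adjusted over the list alone (adjusted p = 0.00752 and 0.0469). Adjusted p was 0.135 and 0.249 with an estimated correlation, and in females it was 0.0632 without E9.5 replicate 2.

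Glycolysis genes fell in both sexes: 9 of 16 lower and 2 higher in males and 10 lower and 1 higher in females, the same adjusted over the list alone (adjusted p = 0.000502 and 4.31e-06; adjusted p = 0.0460 and 0.0317 with an estimated correlation). Besides Ldha they included the triosephosphate isomerase gene Tpi1, from 243 ± 7.26 RPM to 45.7 ± 1.65 RPM in males and 56.6 ± 1.09 RPM in females, and the glucose transporter gene Slc2a3, from 390.3 ± 33.0 RPM to 65.5 ± 3.69 RPM and 125 ± 22.7 RPM. Of 22 imprinted genes, 14 were lower and 3 higher in males (adjusted p = 4.45e-07; 15 and 3 adjusted over the list alone). In females 11 were lower and 4 higher (adjusted p = 0.0250; the same adjusted over the list alone). Adjusted p was 0.0176 and 0.0856 with an estimated correlation. The imprinted gene Mest fell to 27.1 ± 7.08 RPM in females from 446 ± 5.98 RPM. The E9.5 libraries also held transcripts of genes typical of other tissues, described below. How far RNA of other cells contributed to the falls of glycolysis and imprinted genes was not tested. Of 12 p53 targets, 7 were higher and 1 lower in males, the same adjusted over the list alone (adjusted p = 0.00752, and adjusted p = 0.261 with an estimated correlation). In females against E9.5 the p53 list did not pass. Cdkn1a, the p21 cell cycle inhibitor gene, rose from 7.08 ± 0.658 RPM to 33.3 ± 2.40 RPM in males and 41.3 ± 5.45 RPM in females. Trp53, which encodes p53, rose from 23.5 ± 28.2 RPM (43.4 and 3.54 RPM in the libraries) to 305 ± 32.2 RPM in males.

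The E9.5 libraries also carried transcripts of genes typical of other tissues. The embryonic globin gene Hbb-y (NCBI gene 15135, chromosome 7, 103851754 to 103853207) fell from 1767 ± 138 RPM to 7.49 ± 2.19 RPM in males and 8.30 ± 2.84 RPM in females. Globin genes summed to 4565 RPM and 4035 RPM at E9.5 and to at most 18.4 RPM in any other library. Blood and endothelium genes fell (7 of 9 in each sex, 1 higher in females, the same adjusted over the list alone; adjusted p = 1.92e-07 and 1.86e-07; adjusted p = 0.0373 and 0.0317 with an estimated correlation). Fibroblast and stromal genes fell in 10 of 12 in males and 8 of 12 in females (adjusted p = 8.89e-07 and 7.23e-05; adjusted p = 0.0176 and 0.0317 with an estimated correlation; 10 and 9 adjusted over the list alone). The collagen gene Col3a1 fell from 63.5 ± 3.55 RPM to 1.68 ± 0.172 RPM and 1.23 ± 0.0315 RPM. Hindgut and endoderm genes fell in 5 of 7 in males and 4 of 7 in females, with 1 higher in females (adjusted p = 0.00328 and 0.0259; adjusted p = 0.0525 and 0.133 with an estimated correlation). Adjusted over the list alone, 5 fell and 1 rose in males and 4 fell and 1 rose in females. Afp, the alpha-fetoprotein gene, fell from 18.3 ± 3.50 RPM to 0.151 ± 0.213 RPM and 0. Mesoderm genes fell in males, 4 of 6 and the same adjusted over the list alone (adjusted p = 0.00519, and adjusted p = 0.0525 with an estimated correlation). In females 2 of 6 mesoderm genes fell, with a median of 0.07 on the log2 scale, and the list did not pass (adjusted p = 0.506).

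Leaving out 1 library lowered these counts, in males to 2515 without E9.5 replicate 1, 2509 without E9.5 replicate 2 and 2649 without E12.5 male replicate 2, and in females to 2512 and 2456 without E9.5 replicate 1 and replicate 2. Both embryonic contrasts share the E9.5 libraries. Their log2 changes correlated across genes at r = 0.794. Noise simulated with shared libraries alone gave 0.50, a value fixed by the sharing whatever the size of the noise. It therefore does not measure a part of the 0.794. The covariance of the changes was 0.730, against 0.0421 in that simulated noise. In both sexes 1452 genes were higher and 1182 lower.

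**Figure D3:**
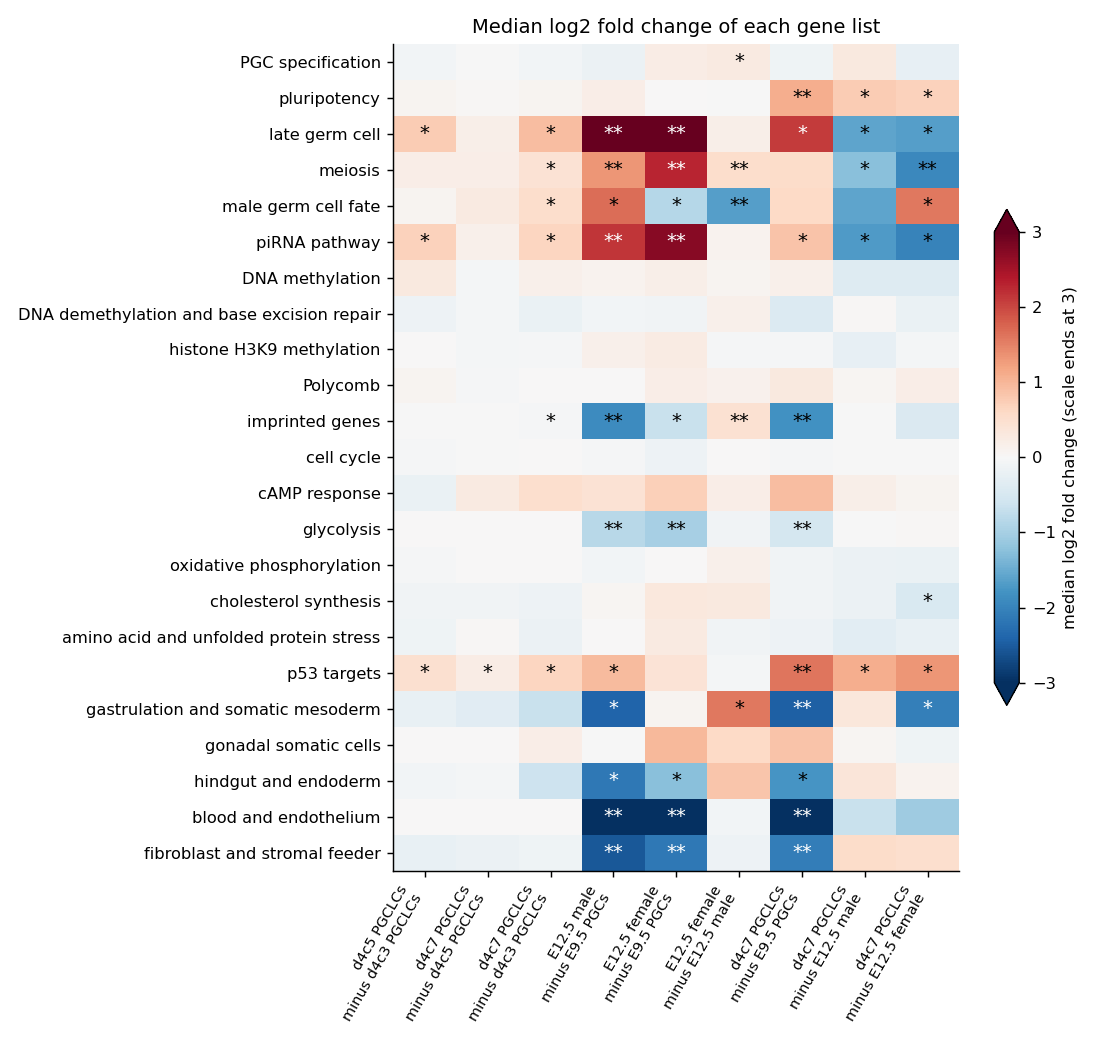
Median log2 fold change of 23 fixed gene lists (vertical) in each of 9 comparisons (horizontal); 1 star marks an adjusted p under 0.05 in camera with the preset correlation, 2 stars also with an estimated correlation. Colours end at 3 on the log2 scale; late germ cell genes reach 3.52 in males and 3.28 in females against E9.5, and blood and endothelium genes -6.11 and -7.04.

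Next, E12.5 female germ cells were compared with male germ cells. Phlda2 was at 479 ± 15.5 RPM in females and 5.67 ± 0.0661 RPM in males, a log2 difference of 6.17 ± 0.14 (SE). Other genes higher in females were Id1, a target of BMP signalling (147 ± 11.2 RPM against 4.44 ± 0.533 RPM), and the transcription factor gene Gata2 (176 ± 1.62 RPM against 12.7 ± 1.18 RPM). So were Nr6a1, which encodes germ cell nuclear factor (165 ± 14.0 RPM against 17 ± 3.67 RPM), and the X-linked gene Porcn, needed for Wnt secretion (169 ± 17.8 RPM against 11.2 ± 2.09 RPM). Lefty2 and Lefty1 were lower in females, by log2 differences of -6.66 and -5.54. Pmaip1 was at 41.6 ± 3.06 RPM in males and 0.919 ± 0.300 RPM in females.

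Between the sexes 1297 genes were called, 725 higher and 572 lower in females, and 650 of them differed at least 2-fold. Of 409 X-linked genes 117 were higher and 5 lower in females (camera, adjusted p = 3.29e-13, and adjusted p = 0.00153 with an estimated correlation; 142 and 13 adjusted over the list alone), with a median log2 difference of 0.43. Of 16 meiosis genes 5 were higher, the same adjusted over the list alone (adjusted p = 0.00116, and adjusted p = 0.0437 with an estimated correlation), among them Stra8. Rec8, the meiotic cohesin gene (NCBI gene 56739, chromosome 14, 55618002 to 55625395), was at 49.9 ± 8.0 RPM against 2.94 ± 1.60 RPM. Male fate genes were lower, 5 of 7 with 1 higher, the same adjusted over the list alone (adjusted p = 7.69e-06, and adjusted p = 0.0437 with an estimated correlation). They included Nodal, 7.81 ± 2.47 RPM against 26.5 ± 5.59 RPM in males. Nanos2, a male fate gene below the filter, was at 1.88 and 1.81 RPM in the male libraries and at 0 and 0.251 RPM in the female libraries, within the 0.754 to 0.909 RPM that a value of 0 allows there.

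Imprinted genes were higher in females, 8 of 22 with 1 lower, the same adjusted over the list alone (adjusted p = 0.00116, and adjusted p = 0.0437 with an estimated correlation). Besides Phlda2, Igf2 was at 32 ± 4.13 RPM against 5.52 ± 0.287 RPM, and Mest was lower at 27.1 ± 7.08 RPM against 81.8 ± 4.33 RPM. PGC specification genes were shifted upward in females (4 of 14 higher, 1 lower; 6 and 1 adjusted over the list alone; adjusted p = 0.0238, adjusted p = 0.594 with an estimated correlation, and adjusted p = 0.0693 without E12.5 male replicate 1). Their members included Tfap2c, a transcription factor of PGC specification, at 140.4 ± 15.9 RPM against 64.7 ± 11.1 RPM, and Dppa3, which was lower in females. Mesoderm genes were higher, 3 of 6 with 1 lower, the same adjusted over the list alone (adjusted p = 0.0223, and adjusted p = 0.131 with an estimated correlation), among them the homeobox gene Msx2 at 73.4 ± 2.57 RPM against 6.40 ± 2.87 RPM. Without any 1 of the 4 libraries fewer genes were called: 552 and 567 without male replicate 1 and replicate 2, and 538 and 562 without female replicate 1 and replicate 2.

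The fourth question was whether genes that differ between the E9.5 and E12.5 libraries move the same way in culture. Of the 1452 genes higher and 1182 lower at E12.5 than at E9.5 in both sexes, 66.5% changed with the same sign from d4c3 to d4c7 (71.0% of the higher and 60.9% of the lower). Without a filter the share of the lower set was 46.3% and that of the higher set was 71.4%. A gene without any change, such as one at 0 in all d4c3 and d4c7 libraries, counted as not falling. The 46.3% therefore does not say that most of the lower set rose. In that setting both sets kept their directions in camera (p of at most 0.000426). The lower set also held 36 of 54 tested markers of other tissues that fell from E9.5 and the higher set 0. Without these markers 61.5% of the lower set fell, and other-tissue genes outside these lists stayed in it. The first set was shifted upward and the second downward (camera, p = 2.83e-09 and 5.69e-06; p = 0.000124 and 0.000853 with an estimated correlation, over exact sets of genes chosen on the embryonic libraries of this series). Dazl, Hormad1, Smc1b and Ddx4 rose in both settings. Among the embryonic genes called in culture, 91 of the higher set rose and 5 fell, and 42 of the lower set fell and 6 rose. Medians were small, 0.17 and -0.11 on the log2 scale, against 0.016 for all tested genes. Without d4c7 replicate 2 the share was 60.6%. Across all 10856 genes the culture change and the mean embryonic change correlated at Pearson r = 0.272 and Spearman rho = 0.234, and genes are not independent replicates. Since the sets were chosen on libraries of this series, their shift is not evidence from an independent study.

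Finally, d4c7 PGCLCs were compared with each embryonic group. Against E9.5, Dazl was higher in PGCLCs (400.3 ± 147 RPM against 11.2 ± 2.43 RPM). Fabp3, which encodes a fatty acid-binding protein, was at 196 ± 15.3 RPM against 1.86 ± 0.0345 RPM. Also higher were the serine protease gene Htra1 (108 ± 55.2 RPM against 0.669 ± 0.613 RPM) and the pluripotency genes Dppa2 (138 ± 52.3 RPM against 17.2 ± 2.25 RPM) and Dppa4 (549 ± 208 RPM against 87.5 ± 1.03 RPM). Dnmt3l (NCBI gene 54427, chromosome 10, 78042287 to 78063622) was at 110 ± 97.0 RPM in PGCLCs and listed at 0 in all 6 embryonic libraries. The de novo methyltransferase gene Dnmt3b was higher (32.1 ± 15.4 RPM against 6.35 ± 1.70 RPM), and Uhrf1, a maintenance methylation factor, was lower (10.2 ± 2.82 RPM against 28.3 ± 3.64 RPM; adjusted p = 0.0629 without E9.5 replicate 1). Igf2 (2.31 ± 1.60 RPM against 175 ± 4.58 RPM), Grb10 and Ldha (22 ± 8.38 RPM against 630.0 ± 14.2 RPM) were lower, and the 5 globin genes named by the rule, such as Hbb-y, were listed at 0 in d4c7.

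Against E9.5, 3463 genes were called, 1965 higher and 1498 lower, and 1909 at least 2-fold. With medians of log ratios set to 0 there were 1692 higher and 1821 lower, and without d4c7 replicate 2, 1990 and 2007. All 12 p53 targets were higher, the same adjusted over the list alone (camera, adjusted p = 1.59e-09, and adjusted p = 0.0342 with an estimated correlation). Trp53inp1 (NCBI gene 60599, chromosome 4, 11156441 to 11174379) was at 237 ± 0.125 RPM against 33.3 ± 1.90 RPM, and the cyclin G1 gene Ccng1 at 202 ± 50.2 RPM against 26.5 ± 1.06 RPM. Pluripotency genes were higher, 14 of 18 with 1 lower, the same adjusted over the list alone (adjusted p = 3.41e-06, and adjusted p = 0.0342 with an estimated correlation). Late germ cell genes were higher, 12 of 17, the same adjusted over the list alone (adjusted p = 6.38e-08, and adjusted p = 0.100 with an estimated correlation). Of 12 piRNA genes 5 were higher, 6 adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.171 with an estimated correlation).

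Lower than at E9.5 were 12 of 22 imprinted genes with 5 higher, the same adjusted over the list alone (adjusted p = 0.000135), and 8 of 16 glycolysis genes with 2 higher, 9 and 2 adjusted over the list alone (adjusted p = 0.000161). Adjusted p was 0.0342 and 0.0356 with an estimated correlation. How far RNA of other cells in the E9.5 libraries contributed to these 2 differences was not tested. The lists of other tissues were also lower in d4c7. Among them, the mesoderm list had not passed in females against E9.5, although globin genes fell there. Lower were 6 of 9 blood and endothelium genes (1 higher), 6 of 6 mesoderm genes, 8 of 12 fibroblast and stromal genes (1 higher) and 5 of 7 hindgut and endoderm genes (2 higher). Counts were the same adjusted over the list alone. Their adjusted p were 6.55e-07, 1.96e-05, 0.000884 and 0.0365, and with an estimated correlation adjusted p = 0.0342 for the first 3 and 0.153 for hindgut and endoderm. The count was 2069 without E9.5 replicate 1 and 2134 without E9.5 replicate 2.

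Against E12.5 germ cells, Ddx4 was lower in d4c7 PGCLCs, at 98.5 ± 27.8 RPM against 427 ± 2.98 RPM in males and 446 ± 1.01 RPM in females. Mael was at 24.1 ± 10.4 RPM against 149.5 ± 5.79 RPM and 188 ± 14.9 RPM, and Dazl at 400.3 ± 147 RPM against 1174 ± 15.4 RPM and 1218 ± 38.2 RPM. Stra8, at 9.89 ± 1.56 RPM in d4c7, was higher than in males (0.776 ± 0.671 RPM) and lower than in females (37.5 ± 0.695 RPM). Slc25a31, which encodes a germ cell ADP/ATP carrier, was at 10.6 ± 2.27 RPM against 136 ± 14.8 RPM and 150.1 ± 2.17 RPM. Higher in PGCLCs were Fabp3, the glucose transporter gene Slc2a3 (673 ± 194 RPM against 65.5 ± 3.69 RPM and 125 ± 22.7 RPM) and Nanog, a core pluripotency factor gene (300.4 ± 9.76 RPM against 95.7 ± 8.40 RPM in males). Phlda2 at 26.7 ± 3.26 RPM was above males (5.67 ± 0.0661 RPM) and below females (479 ± 15.5 RPM).

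Against males 3968 genes were called, 2058 higher and 1910 lower in PGCLCs (1893 at least 2-fold), and against females 4221, 2154 higher and 2067 lower (2059 at least 2-fold). Without d4c7 replicate 2 more were lower than higher, 2296 against 2035 for males and 2364 against 2044 for females. Late germ cell genes were lower, 9 of 17 against males and 12 of 17 against females (camera, adjusted p = 2.80e-05 and 4.14e-07; adjusted p = 0.255 and 0.136 with an estimated correlation; 9 and 14 adjusted over the list alone). Of 12 piRNA genes 8 and 9 were lower (adjusted p = 0.000400 and 0.000113; adjusted p = 0.248 and 0.136 with an estimated correlation; 8 lower, and 9 lower with 1 higher, adjusted over the list alone). Meiosis genes were lower, 10 of 16 with 2 higher against males (adjusted p = 0.0175; 11 and 3 adjusted over the list alone) and 13 of 16 against females (adjusted p = 4.14e-07; 15 adjusted over the list alone). With an estimated correlation adjusted p was 0.248 for males and 0.0240 for females, and without d4c7 replicate 2 it was 0.0617 for males.

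The p53 targets were higher in PGCLCs, 10 of 12 against males and 11 of 12 with 1 lower against females (adjusted p = 0.000128 and 2.20e-06; adjusted p = 0.248 and 0.120 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower against males and 11 and 1 against females. Pluripotency genes were also higher, 12 of 18 with 2 lower and 13 of 18 with 2 lower, the same adjusted over the list alone (adjusted p = 0.00172 and 0.000588; adjusted p = 0.248 and 0.120 with an estimated correlation). Against females, male fate genes were higher (5 of 7, 1 lower, the same adjusted over the list alone; adjusted p = 0.00303, and adjusted p = 0.136 with an estimated correlation). Mesoderm genes were lower (5 of 6, the same adjusted over the list alone; adjusted p = 0.00380, and adjusted p = 0.120 with an estimated correlation). Cholesterol synthesis genes were also lower (7 of 18, the same adjusted over the list alone; adjusted p = 0.0291, adjusted p = 0.428 with an estimated correlation, and adjusted p = 0.0553 without E12.5 female replicate 2). The counts were 2552 for males without E12.5 male replicate 2 and 2807 for females without E12.5 female replicate 1.

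Over all comparisons 59 of 208 list tests passed. The lists that passed in no comparison were DNA methylation (lowest adjusted p = 0.198), DNA demethylation and base excision repair (0.0935), histone H3K9 methylation (0.379), Polycomb (0.223), cell cycle (0.157), cAMP response (0.157), oxidative phosphorylation (0.0986), amino acid and unfolded protein stress (0.0726) and gonadal somatic cells (0.458), the lowest of 9 comparisons for each list. Single members of these lists were called. Tdg, the thymine DNA glycosylase gene, fell from 134 ± 4.18 RPM at E9.5 to 37.2 ± 3.81 RPM in males and 44.4 ± 3.38 RPM in females, and Tet1, a 5-methylcytosine dioxygenase gene, rose from 50.5 ± 1.69 RPM to 127 ± 1.72 RPM in males. In 33 of the 208 tests the list's median, its mean and the direction of the test differed in sign, and none of these passed.

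Chromosome medians differed between PGCLC replicates. Medians were taken over genes with a mean of at least 20 RPM, as log2 expression relative to the mean of all libraries. The 216 such genes of chromosome 16 had medians of 0.30, 0.33 and 0.27 in replicate 1 of d4c3, d4c5 and d4c7, and of 0.14, 0.05 and -0.09 in replicate 2. Embryonic libraries lay between -0.20 and -0.14. The 289 genes of chromosome 3 had medians of 0.06, 0.17 and 0.25 in replicate 2. The other 17 autosomes lay between -0.10 and 0.11 in every library. The 202 X-linked genes had medians of 0.35 and 0.30 in females and -0.19 and -0.20 in males.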

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

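The tests of whole-chromosome gains, of strain, of feeder RNA, of the p53 list without chromosomes 3 and 16, and of red cell genes above the floor, were chosen after the results were seen. Those of whole added marker lists and of GC content were written down beforehand.

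In 51 genes the change from the E9.5 cells, whose sex could not be read, was called in opposite directions in males and females. Opposite calls in the same model fix the sign of the difference between the sexes, so that the direct test, which all 51 passed, adds little. Of them 20 were higher in males and 31 in females. Female minus male log2 differences were -5.54 for Lefty1, -6.66 for Lefty2 and 6.17 for Phlda2.

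The ERCC spike-in values, used in no comparison, differed between groups. They summed to 12107 RPM in E12.5 female replicate 1, the lowest E12.5 library, and to 16494 RPM in E12.5 male replicate 2, the highest. At E9.5 the sums were 1372 RPM in replicate 1 and 628 RPM in replicate 2, of which the single spike ERCC-00145 gave 1143 RPM and 477 RPM. The sums were 59.6 to 72.7 RPM in the 5 PGCLC libraries with ERCC values, and d4c7 replicate 2, the deepest library, had none. Without ERCC-00145 the sums were 229 and 152 RPM at E9.5 and 12030 to 16407 RPM at E12.5. Labels give 1 ng of RNA for both stages. Differences in spiking or library preparation were not tested. They are therefore not separated from stage in the contrasts of E12.5 with E9.5, nor from the effect of leaving out d4c7 replicate 2.

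Blood, stromal and gut genes were high in both E9.5 libraries, with Hbb-y at 1767 ± 138 RPM and Hba-x at 1215.5 ± 151 RPM (SD, n = 2). RNA of embryonic red blood cells may have contributed: 14 of 20 added red cell genes were highest at E9.5, against a median of 4 and a maximum of 11 in 10000 expression-matched random lists, with 3 of the 20 also at 5 RPM or more in PGCLCs. Of the 14, 9 had E9.5 means under the highest floor of 1.36 RPM, and the other 5 compare with a median of 1 and a maximum of 9 in random lists (percentile 98.9), so this evidence is weak, with sums of 92.5 and 96.5 RPM at E9.5 against 19.6 to 61.7 RPM elsewhere. RNA of other somatic cells of the E9.5 embryo may have contributed too: 19 of 23 added mesenchyme, heart and somite genes were highest at E9.5, against a median of 5 and a maximum of 13, with 1 of the 23 at 5 RPM or more in PGCLCs, and these genes, with all 19 above that floor, summed to 244 and 243 RPM at E9.5 against 5.82 to 21.2 RPM elsewhere, led by Twist1 (39.3 RPM), Meox1 (35.3 RPM), Tcf15 (27.5 RPM) and Actc1 (24.2 RPM). The sort for Stella-EGFP should remove both kinds of cell, and low transcription of these genes by the PGCs themselves was not tested and stays open.

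Genes of chromosomes 16 and 3 were shifted together between PGCLC replicates, with a median of replicate 1 minus replicate 2 over d4c5 and d4c7 of 0.32 ± 0.03 (SE) and -0.22 ± 0.03 on the log2 scale. Same-number libraries of d4c5 and d4c7 shared deviations, as given below, so these groups are not separate evidence. GC content or expression level of the genes is excluded as the whole cause, since random lists matched on both gave medians of -0.07 to 0.09 and -0.06 to 0.09, and the shifts lay at percentiles 100 and 0. A strain difference between culture and embryo cannot give the 0.37 between d4c7 replicates of 1 strain over chromosome 16, though it stays open for the level of culture against embryo. A median of 0.00880 ± 0.0463 (SE) in the first of 4 parts of chromosome 3 argues against a gain of that whole chromosome. The others had -0.37, -0.33 and -0.10. The bound for this test was set after the parts were seen, and a gain of part of chromosome 3 was not tested. A gain of the whole chromosome 16 in part of the cultured cells may explain the shift of chromosome 16, which was present in all 4 parts (0.30, 0.25, 0.35 and 0.34). But the 2 chromosomes were first predicted together, 6 of 8 parts met that, and they were separated afterwards. Replicate 2 also lay above the embryonic libraries on chromosome 16, at 0.14, 0.05 and -0.09 in d4c3, d4c5 and d4c7 against -0.20 to -0.14. The difference between replicates therefore does not show that replicate 2 lacks such a gain.

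The p53 targets were higher at d4c7 than at d4c3, by a median of 0.64 ± 0.15 (SE) on the log2 scale, and the list passed with each library left out in turn (adjusted p from 2.37e-10 to 3.55e-05, the latter without d4c7 replicate 1). RNA of the stromal feeder cells, which the sort for Blimp1-mVenus should remove, would raise feeder genes too, but their median was -0.14 ± 0.27. The list passed without the genes of chromosomes 3 and 16 (adjusted p = 9.72e-09), but only 1 of its 12 genes lies there, so an indirect effect of their shift could not be told apart from other causes. With an estimated correlation the list did not pass (adjusted p = 0.101). Stress of sorting or of the medium was not tested, and whether longer culture raises p53 activity stays open.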

How the results depend on the processing

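The block within culture libraries, the fit without chromosomes 3 and 16 and the share without markers of other tissues were chosen after the data were seen. No named gene, list or pooled share that was called changed sign under an alternative, but the balance of higher and lower genes did. With medians of log ratios set to 0 the lower genes outnumbered the higher in males (2211 against 1829) and females (2141 against 1949) against E9.5 and in d4c7 against E9.5 (1821 against 1692) and females (2139 against 2117). Without a filter they did so in the first 3 (2440 against 2091, 2248 against 2075, and 1959 against 1913). Without d4c7 replicate 2 they did so for d4c7 against d4c3 (457 against 329), E9.5 (2007 against 1990), males (2296 against 2035) and females (2364 against 2044). The balance of d4c7 against both sexes also turned with quantile normalization and without chromosomes 3 and 16, and that of males against E9.5 with a fold threshold and without male replicate 2. From d4c3 to d4c5, 9 calls became 4 with a pseudocount of 10, 3 without a filter, 17 with a minimum of 20 RPM, 20 with medians of log ratios set to 0, 22 with replicate as a block and 25 with a robust variance model, and leaving out 1 library gave 2 to 26. From d4c5 to d4c7, 2 calls became 1 with a pseudocount of 0.1, a minimum of 20 RPM or no variance trend, limma called 0 without a filter (1054 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 30. From d4c3 to d4c7, 298 became 103 without a filter, 184 without the trend, and 31 to 786 with 1 library left out. A limma fit over the 4 libraries compared called 0, 0 and 0 for these contrasts (805, 262 and 1084 at an unadjusted p under 0.05), and a block within culture libraries 0, 0 and 32 (941, 535 and 1751). Both have fewer degrees of freedom. The 4-library fit, however, called more genes against E9.5 than the main fit, 5338 against 4089 in males and 5275 against 4069 in females. Fewer degrees of freedom therefore do not by themselves lower a count. How much of the loss in culture they explain was not tested. A fold threshold of 1 on the log2 scale, which removes smaller changes by construction, left 2067 genes for males and 1993 for females against E9.5, 650 between the sexes, and 1909, 1893 and 2059 for d4c7 against E9.5, males and females. The 4-library fit gave 2297 and 2456 for the latter pair. With 1 library left out the ranges were 2509 to 2842, 2456 to 2782, 538 to 567, 2069 to 3997, 2552 to 4331 and 2807 to 4408 in the same order, with the lone library assumed to vary like the other groups. The replicate block called 22, 2, 358, 4264, 4230, 1417, 3682, 4141 and 4393 genes over the 9 contrasts. Of 59 list calls 25 held with an estimated correlation. With replicate as a block 56 held and 3 were lost. Without chromosomes 3 and 16, 56 held; those lost were meiosis for d4c7 against males (adjusted p = 0.0800), cholesterol synthesis against females (0.0707) and male fate in females against E9.5 (0.224). The embryonic share of 66.5% ranged from 57.3% without a filter, where the lower set was at 46.3%, to 68.2%, and was 66.8% without markers of other tissues. With 1 library left out it was lowest without d4c7 replicate 2, at 60.6% (61.7% of the higher set and 59.3% of the lower). Genes without any change counted against the share, and without a filter both sets still passed camera in their directions. Of 2428 tests of called named genes with 1 library left out, 1995 kept the call and 433 lost it, and 4 of 120 tests of uncalled ones gained it. Scalings moved the median of all genes by under 0.1. Count tests were not run since whole reads were not recovered, and values near the floor of 0.517 to 1.36 RPM limit what can be seen of rare transcripts.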

Other observations

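The comparison of X-linked genes outside the sexes and the choice of genes that follow were made after their values were seen.

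Against all 3 embryonic groups, 749 genes were higher and 432 lower in d4c7 PGCLCs. Among the higher were Dnmt3l, at 110 ± 97.0 RPM and listed at 0 in the embryo, and Fabp3, at 196 ± 15.3 RPM against 1.84 to 3.31 RPM in embryonic libraries. The protein kinase C gene Prkch was at 92.4 ± 0.324 RPM against 1.52 to 7.72 RPM, Htra1 at 108 ± 55.2 RPM against 0.236 to 8.05 RPM, and Spp1, which encodes osteopontin, at 256 ± 109 RPM against 10.9 to 26.6 RPM. Dnd1 was lower, at 56.0 ± 9.78 RPM against 190.4 to 349 RPM. Chromosome 16 held 51 of the higher genes, 6.99% of those with a position against 3.25% of the tested genes, and chromosome 3 held 45, 6.16% against 4.64%. Culture and embryo also differ in strain, reporter, sort and RNA input.

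X-linked genes, 409 of them tested, were shifted downward in males against E9.5 (camera, adjusted p = 0.0122 over 9 contrasts; median -0.20 on the log2 scale, 77 higher and 134 lower) and upward in females (adjusted p = 0.0465; median 0.28, 140 higher and 69 lower). In d4c7 PGCLCs they were lower than in females (adjusted p = 0.000180; median -0.36), and against males the test gave adjusted p = 0.391 with a median of 0.05. Downward shifts were small against E9.5 (adjusted p = 0.0465, median -0.10), from d4c3 to d4c7 (adjusted p = 0.0380, median -0.07) and from d4c5 to d4c7 (adjusted p = 0.0380, median -0.04). Without d4c7 replicate 2 none of these 3 shifts passed, and their medians were -0.09, -0.03 and -0.02. They also did not pass without some other libraries. Among these were E9.5 replicate 2 for the first shift, d4c3 replicate 1 for the second and either d4c5 replicate for the third. In females against E9.5 the shift did not pass without E9.5 replicate 1 (median 0.26) or E12.5 female replicate 1 (median 0.29). Nor did it pass without d4c3 replicate 1, either d4c5 replicate or d4c7 replicate 2, which lie outside that contrast. From d4c3 to d4c5 adjusted p was 0.338. Over all libraries the shifts above passed with an estimated correlation, with adjusted p from 0.00870 to 0.0474. Xist, the RNA that silences an X chromosome, was below the filter, at 6.99 and 3.54 RPM in the E9.5 libraries and at most 1.03 RPM elsewhere, with 0.606 and 0.503 RPM in females. The sex of the E9.5 cells and of the PGCLC line could not be read, since no Y-linked gene had a row. Sex therefore cannot be told apart from stage or culture in the X-linked shifts between PGCLCs, E9.5 and E12.5 cells.

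Across genes, replicate 1 minus replicate 2 in d4c5 correlated with the same difference in d4c7 at r = 0.455, and at 0.442 without chromosomes 3 and 16. It was 0.116 for d4c3 with d4c5 and 0.131 for d4c3 with d4c7, and genes are not independent replicates. Libraries of d4c5 and d4c7 with the same number correlated at 0.981 (replicate 1) and 0.979 (replicate 2). Replicates within d4c5 and within d4c7 correlated less, at 0.973 and 0.965. Same-number libraries of these 2 groups therefore shared deviations, which the main contrasts did not model. The labels do not say whether replicate numbers link libraries.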
